A study of Oncorhynchus mykiss with 36 samples.

How the data were processed

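RNA was measured by sequencing in 36 libraries of whole rainbow trout sac-fry, 18 at 0 and 18 at 14 days post-hatch, from mothers on 3 diets, 3 families and 2 sires. Total RNA was extracted with a column kit and made into stranded libraries. Per the submitters' processing notes, the tools were Salmon 0.14.1 and DESeq2 (version not given). The authors' genome build is not given in the sources used here. Of the positions of genes only their length on the genome was used. Every gene name in the tables matched a name of the RefSeq annotation. Of these 33201 of 43128 genes at 0 dph and 33158 of 43100 at 14 dph carried only a LOC number.

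The deposited signal values are normalized counts per gene and library, made by the authors within each age by dividing by a factor per library and by factors specific to each gene. They are not whole multiples of a step, so reads cannot be recovered and no filter on reads was applied. Because the ages were normalized apart, no value was compared between ages. Per the file headers, the 24 comparison tables of the authors hold log2 fold changes with standard errors and p-values with adjusted p-values from their own test, over all families, in each family and in each sire. The other 22 tables carry the same values per library as the 2 tables used here, and 0 sample columns were left unmatched. Low A1 at 0 dph was matched by its code alone, since the sample number in its description differs from that of its column. A key of abbreviations was read but holds no measurement.

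Groups, comparisons, gene lists, thresholds, the rule for named genes and most of the other settings were set before the data were examined. High against Medium and Low against Medium were fitted at each age with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean per diet, empirical Bayes moderation with a trend on the mean level, no filter and Benjamini-Hochberg adjustment over all genes of a comparison. Genes with an adjusted p under 0.05 were called. Each family (2 libraries per diet) and each sire (3 per diet) was fitted alone in the same way. Cell-means fits of 9 diet and family cells or 6 diet and sire cells, which pool the spread over the 18 libraries of an age, gave the interaction tests. Within a family no exact test of 2 against 2 libraries could reach 0.05, so limma, which borrows the spread from all genes, was used. These p-values measure only the spread between these samples. Values are means ± SD of 6 libraries, and fold changes carry ± SE, unless stated otherwise.

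Of 30 fixed gene lists, grouped as methyl group and choline metabolism, lipid metabolism, energy, growth, protein turnover, stress, immunity and tissue markers, 29 had at least 5 measured members. These were tested with camera (preset correlation 0.01, two-sided, adjusted over 29 lists and 4 comparisons). Camera with an estimated correlation, fry and an exact two-sided permutation test of 6 against 6 list means over members with a mean of at least 10 were run beside it. Neither fry's one-way nor its mixed test compares a list with other genes, and fry called 0 lists. Members were also adjusted over the list alone, with no correction for the number of lists and comparisons. Some such calls are therefore expected by chance over 30 lists and 4 comparisons. Lists were matched by gene symbol, so genes with only a LOC number were in no list. The rule set beforehand also allowed a LOC gene whose product gives the symbol of a member, but this step was not done. Named genes were, by the rule, up to 10 per direction with an adjusted p under 0.05, a mean of at least 10, an informative name and the same sign in all 3 families. Within families and sires it took up to 3 per direction without the sign condition. It also took up to 10 with the smallest p in each interaction test and up to 4 members with the smallest p of each list. Since limma called no gene over all families, the first part named none there.

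On data simulated from these libraries, with 200 genes changed, 6 against 6 libraries recovered 16.5% of changes of log2 1, 62% of log2 2 and 86% of log2 3 at 0 dph, and 34%, 75% and 87.5% at 14 dph. With 2 against 2 libraries a family fitted alone recovered 0% except 7.5% at log2 3 at 14 dph. The 9-cell fit recovered 0%, 4% and 46% at 0 dph and 0%, 23% and 62.5% at 14 dph. The interaction test, with 1 family changed, recovered 0%, 0% and 12.5% and 0%, 0% and 37.5%. The number of unchanged genes called was 0 to 8. The simulated spread was that within diet and family cells, so differences between families were left out. The main fit keeps these in its spread, so the shares for 6 against 6 libraries may be too high. A shifted list was called at both ages, and 0 of 19 other lists were. These lists were drawn from genes at random, so they need not share the correlation within the fixed lists, such as an estimated 0.787 for ribosomal proteins at 0 dph. The simulation therefore does not show how often the preset test calls an unchanged fixed list.

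Libraries were checked for their sum, ribosomal RNA share, span correlation, tissue lists and correlation with the others (median Spearman from 0.866 to 0.943 at 0 dph and from 0.83 to 0.944 at 14 dph), and 0 pairs were identical. The numbers that family and sire share across diets were tested as pairs. Libraries of the same number correlated above 0.1 in 10 of 18 pairs at 0 dph and 7 of 18 at 14 dph. Their median correlation was 0.156 against −0.0319 for other pairs at 0 dph, and 0.0637 against −0.0114 at 14 dph. The closest library of another diet had the same number for 7 of 18 libraries at 0 dph and 8 of 18 at 14 dph. Libraries of the same number were thus somewhat more alike. The main fit did not treat them as pairs, and the fit with them as a block is an alternative. No sequencing batch or date is given in the sources used here.

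The alternatives were other thresholds (0.1 and 0.01), a minimum fold change, a minimum mean of 10, a pseudocount of 0.5, scaling by a trimmed mean, the block for genes, each library or family left out, a larger SE, another preset correlation and ranks for the lists. Chosen after the data were seen were library weights, a liver covariate, a span covariate, the block for lists, swaps within family and sire, the exact test of list means, the fits without the doubted libraries, the pooled fits, the estimated correlation and the authors' deposited adjusted p. Scaling by edgeR's own trimmed mean needs counts, so it was computed on the normalized values. Splits of the samples were drawn 100 times where there were more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.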

Results

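RNA was sequenced from sac-fry of rainbow trout whose mothers had been fed 2065 ppm (Low), 5657 ppm (Medium) or 9248 ppm (High) choline. Choline is used to make phosphatidylcholine and, through betaine, to supply methyl groups. Fry of 3 families (A, B and E) and 2 sires were sampled at 0 and at 14 days post-hatch (dph). The 36 libraries formed 6 groups of 6, with 1 library per family and sire in each diet and age. The diets were given to the mothers, whose number the sample labels do not give. Libraries of the same diet and family may share a mother, so 6 libraries need not stand for 6 mothers. Within a family, a difference between mothers could then not be told apart from diet. A library is named by its diet, family and sire (High E1). The questions were how choline supplementation (High against Medium) and restriction (Low against Medium) of the mother altered the offspring's transcripts, and whether family or sire altered that response. The sum of normalized counts per library, in units of 1000000, was 28.4 to 90.2 over 43128 genes at 0 dph and 22.1 to 57.9 over 43100 genes at 14 dph. Whole read counts cannot be recovered from these values, so the depth in reads is unknown and no counting interval is given. Ribosomal RNA genes took 4.03% to 54.6% of the sum at 0 dph and 4.59% to 50.7% at 14 dph. The mean of the liver transcripts, given as log2 relative to the median of the 18 libraries of an age, ran from −3.35 to 1.86 at 0 dph and from −3.35 to 0.82 at 14 dph. It was below −2 in High E1, High E2, Low B2 and Low E1 at 0 dph and in High A1, Medium A1 and Low E1 at 14 dph. Ribosomal RNA was above 45% in High B2 at 0 dph and in Medium B1 and High A1 at 14 dph. These 5 libraries at 0 dph and 4 at 14 dph are called the doubted libraries. The span correlation was taken as a possible sign of RNA quality. It is the Pearson correlation across protein-coding genes of a library's deviation from the median library with the log2 length of the gene on the genome. No direct measure of RNA quality was used. It was computed from the same values as the gene lists, so fits with it as a covariate are not independent of the lists. The span correlation ran from −0.397 to 0.308 at 0 dph and from −0.178 to 0.264 at 14 dph. Its mean in Medium, High and Low libraries was −0.0166, −0.0459 and 0.0642 at 0 dph and −0.0176, 0.0132 and 0.0333 at 14 dph.

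At hatch, igfbp1, which encodes a protein of liver origin that binds insulin-like growth factors, was lower in fry of High mothers. It averaged 5.41 ± 12.3 normalized counts (SD, n = 6) against 25.7 ± 10.4 in Medium fry, a log2 fold change of −3.50 ± 0.78 (SE). In 5 of 6 High libraries it lay below all Medium libraries. It is listed at 0 in High A2, High B2 and High E1, and at 30.5 in High B1. Cholesterol synthesis genes rose as a list, by a test that assumes a preset correlation between members (adjusted p = 0.0186; adjusted p = 0.972 with an estimated correlation). Of 18 members 15 had a fold change above 0, and the difference of list means was 0.18 ± 0.20. Its members hmgcra, the rate-limiting reductase of the pathway (2023 ± 634 against 1379 ± 482), hsd17b7 (0.60 ± 0.27) and fdps (0.35 ± 0.21) did not pass on their own. Liver transcripts fell as a list by the same test (adjusted p = 0.972 with an estimated correlation), with 19 of 21 members below 0 and a difference of list means of −0.85 ± 0.98. Among them were the retinol carrier rbp4 (−1.02 ± 0.58), ambp (−1.15 ± 0.84) and fetub (−1.05 ± 0.81), none of which passed.

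The liver difference in this comparison lay in 1 family. It was 0.37 in family A, 0.57 in family B and −3.50 in family E. High E1 and High E2 held the fewest liver transcripts of the High group (−2.97 and −3.35). Without the doubted libraries the liver list rose (adjusted p = 1.45e-07), and it also rose without family E (adjusted p = 0.0196), both by the test with the preset correlation. High E1 and High E2 were doubted for their low liver mean, so the first of these results was largely fixed by that choice. The cholesterol difference was 0.56 in family A, −0.31 in family B and 0.28 in family E. In 5 of 6 High libraries the list lay above the Medium mean, and in 3 above all Medium libraries. The list's call ended without family A (adjusted p = 0.792), without family E (adjusted p = 0.202) and with the span correlation as a covariate (adjusted p = 0.0767). Of 15 genes of choline uptake and phosphatidylcholine synthesis 4 were above 0 and 11 below (adjusted p = 0.709). The ethanolamine kinase etnk1 had the smallest p among them (0.43 ± 0.20, adjusted p = 0.632 over the list). Other list members with values were the growth regulator tsc2 (1.40 ± 0.65), the cytokine suppressor socs2 (−0.67 ± 0.32) and the fatty acid carrier fabp4b (0.67 ± 0.26, adjusted p = 0.352 over the list).

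Limma called 0 of 43128 genes for supplementation at 0 dph, and 953 had an unadjusted p under 0.05, 476 up and 477 down. The authors' deposited table lists 19 with an adjusted p under 0.05, 15 up and 4 down. The fold changes of the authors' 4 tables over all families differ from those at a reference family or sire by a median of 0.0163 to 0.0281, and from the mean over families and sires by 0.136 to 0.485. Their counts are therefore not for the same comparison as the limma fit. The call of igfbp1 was adjusted over the list alone, the 28 genes of growth hormone, insulin-like growth factor and insulin signalling (adjusted p = 0.00678; 1 over all genes tested). Without the doubted libraries, with 3 High and 6 Medium libraries left, its fold change was −2.63 ± 0.95 and it was not called (adjusted p = 0.414). The fold change was smaller and its SE larger. The camera test with a preset correlation called 2 of 29 lists, cholesterol synthesis (adjusted p = 0.0186) and liver (adjusted p = 0.00223). No list call of the 4 comparisons over all families held with an estimated correlation (adjusted p of 0.972 or more for every list).

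In fry of Low mothers at hatch, igfbp1 was also lower, at 2.47 ± 2.79 against 25.7 ± 10.4 normalized counts (log2 fold change −3.38 ± 0.78, n = 6 per diet). Both contrasts use the same Medium libraries, so the Low and High results for igfbp1 are not independent. For igfbp1 all 6 Low libraries lay below all Medium libraries. It is listed at 0 in Low A2, Low B2 and Low E1. The pattern recognition receptor tlr2, near the floor, averaged 4.32 ± 2.27 against 0.490 ± 0.877 (1.87 ± 0.46). In 4 of 6 Low libraries it lay above all Medium libraries. Liver transcripts fell as a list (19 of 21 members below 0, difference of list means −1.55 ± 0.58), by the preset test and not with an estimated correlation (adjusted p = 0.972). The difference was −1.11, −1.61 and −1.91 in families A, B and E, and all 6 Low libraries lay below the Medium mean. In 4 of 6 the list lay below all Medium libraries. Examples were rbp4 (480 ± 171 against 1300 ± 525), ambp (−1.84 ± 0.84), heparin cofactor serpind1 (−1.43 ± 0.66) and prothrombin f2 (−1.56 ± 0.75), each at an adjusted p of 0.167 over the list. Innate immune and acute phase genes, many of them made by liver, fell as a list as well (25 of 32 below 0, −0.94 ± 0.38; adjusted p = 0.972 with an estimated correlation). In 5 of 6 Low libraries the list lay below the Medium mean and below all Medium libraries. The chemotactic factor lect2 averaged 63.0 ± 40.9 against 597 ± 988. The complement genes c9 and c5 had fold changes of −2.33 ± 0.95 and −1.87 ± 0.84, none passing over the list.

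Cytosolic ribosomal protein genes fell as a list in this comparison by the preset test, but not with an estimated correlation (adjusted p = 0.972). All 38 members were below 0, by a difference of list means of −0.33 ± 0.32, with 5 of 6 Low libraries below the Medium mean. Examples were rpl9 (−0.45 ± 0.37) and rps12 (−0.50 ± 0.41). Genes of oxidative phosphorylation fell as a list (35 of 39 below 0, −0.20 ± 0.31; adjusted p = 0.972 with an estimated correlation), with ndufs4 at −0.26 ± 0.21. Genes of lipoproteins and lipid transport fell too (14 of 21 below 0, −0.38 ± 0.24; adjusted p = 0.972 with an estimated correlation), with apom at −1.77 ± 0.73, lcat at −1.12 ± 0.67 and apoa2 at −1.15 ± 0.71. In each of these lists 5 of 6 Low libraries lay below the Medium mean. Fewer lay below all Medium libraries: 4 for ribosomal proteins, 2 for oxidative phosphorylation and 1 for lipoproteins. Genes of skin rose as a list (8 of 8 above 0, 0.51 ± 0.40; adjusted p = 0.972 with an estimated correlation), with the epidermal regulator tp63 at 0.65 ± 0.35 and the keratin krt5 at 0.63 ± 0.43. Genes of cartilage and bone rose as well (19 of 24 above 0, 0.36 ± 0.38; adjusted p = 0.972 with an estimated correlation), with the collagen gene col1a1 at 0.90 ± 0.53. In both 4 of 6 Low libraries lay above the Medium mean, and 4 for skin and 2 for cartilage and bone lay above all Medium libraries. Over the 18 libraries of this age the span correlation had a Spearman correlation of −0.946 with the mean of oxidative phosphorylation genes, −0.792 with ribosomal proteins, −0.695 with lipoproteins and −0.67 with cartilage and bone. The values were −0.55 for innate immunity, −0.525 for skin and −0.325 for liver. With the span correlation as a covariate the oxidative phosphorylation and lipoprotein calls ended (adjusted p = 0.48 and 0.149). Low B2 and Low E1, at −2.26 and −2.70 for the liver list, were the doubted Low libraries. The skin and cartilage calls ended without them and the doubted High libraries (adjusted p = 0.194 and 0.464) and without family B (0.677 and 0.998). The lipoprotein and oxidative phosphorylation calls ended without family E (0.214 and 0.138).

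Limma called 0 of 43128 genes for restriction at 0 dph, and 830 had an unadjusted p under 0.05, 533 up and 297 down. The authors' deposited table lists 20, 11 up and 9 down. Without the doubted libraries limma called 1 gene, LOC110516435, named after its values were seen. It is listed at 0 in all Medium libraries and at 16.5 to 82.5 in the 4 Low libraries left. Adjusted over the list alone, igfbp1 (adjusted p = 0.00978) and tlr2 (adjusted p = 0.0211) were called. Without the doubted libraries, with 4 Low and 6 Medium libraries left, igfbp1 had a fold change of −2.74 ± 0.87 and was not called (adjusted p = 0.194), while tlr2 was (adjusted p = 0.00963). The call of tlr2 ended when any of 7 single libraries was left out and when family and sire were fitted as a block (adjusted p = 0.0665). The 7 list calls of the preset camera test were liver (adjusted p = 9.3e-14), ribosomal proteins (8.82e-08), oxidative phosphorylation (0.000265), innate immunity (0.000604), skin (0.00611), cartilage and bone (0.00839) and lipoproteins (0.00863). For the choline list the test pointed down (adjusted p = 0.869) while its mean and median were above 0 (0.01 and 0.02). Its member pcyt2, which makes the activated form of phosphoethanolamine, had a fold change of 0.56 ± 0.31.

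**Figure D1:**
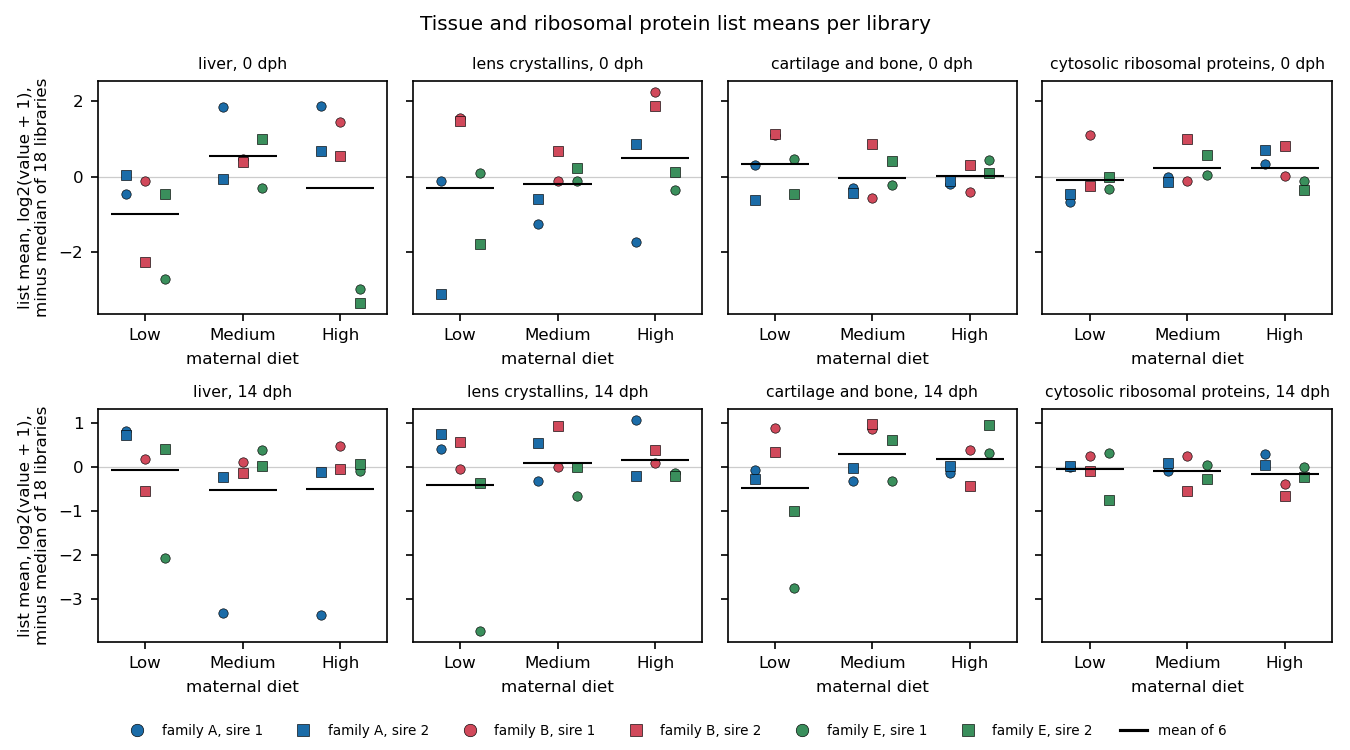
Mean log2 normalized count of 4 gene lists (liver, lens, cartilage and bone, ribosomal proteins) in each library, minus the median of the 18 libraries of its age, by maternal diet at 0 and 14 dph. Colour marks the family, the marker shape the sire and the bar the mean of 6 libraries. At 0 dph the liver list lay between −2.70 and 0.05 in Low libraries and between −0.31 and 1.85 in Medium libraries. At 14 dph Low E1 stood at −3.73 for lens and −2.74 for cartilage and bone.

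At 14 dph, genes of the betaine, methionine and folate one-carbon cycle fell as a list in fry of High mothers by the preset test, but not with an estimated correlation (adjusted p = 0.972). Of 24 members 20 were below 0 and the difference of list means was −0.17 ± 0.0709 (n = 6 per diet). All 6 High libraries lay below the Medium mean, and 2 below all Medium libraries. The enzyme of sarcosine breakdown, sardh, averaged 613 ± 109 against 904 ± 246 normalized counts. The gene mat2aa, which makes S-adenosylmethionine, and mtrr, which reactivates methionine synthase, had fold changes of −0.31 ± 0.16 and −0.39 ± 0.21. None passed over the list. Cell cycle and DNA replication genes fell as a list (19 of 21 below 0, −0.14 ± 0.12; adjusted p = 0.972 with an estimated correlation), with separase espl1 (−0.45 ± 0.18), the mitotic kinase aurka (−0.30 ± 0.20) and cdk2 (−0.26 ± 0.18). So did genes of oxidative phosphorylation (37 of 39 below 0, −0.14 ± 0.17; adjusted p = 0.972 with an estimated correlation), with ndufaf7 (−0.33 ± 0.15) and ndufab1b (−0.39 ± 0.24). In both of these lists 4 of 6 High libraries lay below the Medium mean. Below all Medium libraries lay 3 for the cell cycle and 1 for oxidative phosphorylation. Over the 18 libraries of 14 dph the Spearman correlation with the span correlation was −0.709 for oxidative phosphorylation, −0.391 for one-carbon and −0.133 for cell cycle genes.

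The one-carbon difference was −0.17, −0.29 and −0.07 in families A, B and E. The call ended without family B (adjusted p = 0.33), as did those of oxidative phosphorylation (0.803) and the cell cycle (0.134; 0.137 without family A). Choline list members stood 10 above and 5 below 0 (adjusted p = 0.709). The phosphoethanolamine enzyme pcyt2 averaged 689 ± 292 against 413 ± 119. For selenoi, which joins phosphoethanolamine to a lipid, the fold change was −0.49 ± 0.24, and both had an adjusted p of 0.424 over the list. The yolk precursor vtg3, the single member found by symbol in the hatching enzyme and yolk list, had a fold change of 1.92 ± 0.70 (adjusted p = 1 over all genes tested). With a single member the list allows no adjustment of its own, so it was not called. It was at 0 to 34.3 in High and at 0 to 0.928 in Medium libraries, 5 of 6 of which are listed at 0. Limma called 0 of 43100 genes for supplementation at 14 dph, and 979 had an unadjusted p under 0.05, 564 up and 415 down. The authors' deposited table lists 99, 50 up and 49 down. The preset camera test called 3 of 29 lists (adjusted p = 0.000265 for oxidative phosphorylation, 0.00309 for the one-carbon cycle and 0.00474 for the cell cycle), all down.

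In fry of Low mothers at 14 dph, 2 one-carbon genes were lower. They were called over their list alone and not over all genes. From Medium to Low mat2aa went from 915 ± 177 to 599 ± 134 normalized counts (SD, n = 6, log2 fold change −0.62 ± 0.16). The corresponding values for sardh were 904 ± 246 and 549 ± 116 (−0.70 ± 0.19), with 5 of 6 Low libraries below all Medium libraries for each. The one-carbon list as a whole fell (20 of 24 below 0, −0.24 ± 0.0927; adjusted p = 0.972 with an estimated correlation), with 5 of 6 Low libraries below the Medium mean. Its difference was −0.20, −0.16 and −0.36 in families A, B and E. In 4 of 6 Low libraries the list lay below all Medium libraries. The gene aldh7a1, which oxidizes betaine aldehyde, had a fold change of −0.45 ± 0.15 and the mitochondrial folate enzyme mthfd2l one of 0.75 ± 0.35. Cell cycle and DNA replication genes fell as a list (19 of 21 below 0, −0.35 ± 0.12) by the preset test, and this call too was lost with an estimated correlation (adjusted p = 0.972). The difference was −0.38, −0.18 and −0.48 in families A, B and E, and all 6 Low libraries lay below the Medium mean. In 4 of 6 the list lay below all Medium libraries. The proliferation marker mki67 averaged 1803 ± 372 against 2434 ± 532, the replication licensing gene cdc6 70.6 ± 13.1 against 119 ± 22.3. For top2a and thymidine kinase tk1 the fold changes were −0.48 ± 0.17 and −0.66 ± 0.25, and all of these genes were at an adjusted p of 0.0777 over the list.

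Cartilage and bone genes fell as a list as well (22 of 24 below 0, −0.77 ± 0.58; adjusted p = 0.972 with an estimated correlation). Among them were matn1 (−1.63 ± 0.65), the osteoblast factor sp7 (−1.10 ± 0.45) and col1a1 (10780 ± 9187 against 18560 ± 7973). Their difference was 0.01 in family A, −0.30 in family B and −2.02 in family E. In that family Low E1 and Low E2 stood at −2.74 and −1.01. Fatty acid oxidation genes fell as a list (22 of 26 below 0, −0.21 ± 0.15; adjusted p = 0.972 with an estimated correlation), with acadvl at −0.46 ± 0.16, hadhab at −0.39 ± 0.16 and acaa2 at −0.47 ± 0.20. Oxidative phosphorylation genes fell too (33 of 39 below 0, −0.18 ± 0.17; adjusted p = 0.972 with an estimated correlation). Genes of endoplasmic reticulum and amino acid stress fell as a list (14 of 19 below 0, −0.21 ± 0.12; adjusted p = 0.972 with an estimated correlation), with asns at −0.79 ± 0.37, phgdh at −0.61 ± 0.30 and creld2 at −0.42 ± 0.19. For these lists 4, 5 and 5 of 6 Low libraries lay below the Medium mean, and 2, 1 and 1 below all Medium libraries. The Spearman correlation with the span correlation was −0.598 for fatty acid oxidation and −0.449 for cartilage and bone. With the span correlation as a covariate the oxidative phosphorylation and stress calls ended (adjusted p = 0.0705 and 0.0551). Low E1, with −2.06 for the liver list, was the doubted Low library at this age. Choline list members stood 9 above and 6 below 0 (adjusted p = 0.336). The gene gpcpd1, which releases choline from glycerophosphocholine, averaged 1039 ± 303 against 673 ± 89.0 (adjusted p = 0.061 over the list). For selenoi and etnk1 the values were fold changes of −0.63 ± 0.24 and 0.33 ± 0.15. Genes of other lists with the smallest p were igfbp1 (2.41 ± 0.75, with 3.87, 3.53 and −0.17 in families A, B and E), the stress sensor sesn1 (0.41 ± 0.14), the phosphatidate phosphatase lpin1 (0.81 ± 0.26) and the mevalonate kinase mvk (0.79 ± 0.24), none called.

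Limma called 0 of 43100 genes for restriction at 14 dph, with 0.523 as the smallest adjusted p, and 3425 had an unadjusted p under 0.05, 1617 up and 1808 down. The authors' deposited table lists 174, 63 up and 111 down. Adjusted over the list alone, mat2aa and sardh were called (adjusted p = 0.0215 for each). Leaving out Medium A2 or Medium B2 ended both calls (0.0561 to 0.0735), and leaving out Medium E2 or Low A1 also ended that of sardh. The 6 calls of the preset camera test, all down, were the cell cycle (adjusted p = 8.82e-08), cartilage and bone (9.07e-05), the one-carbon cycle (0.000665), oxidative phosphorylation (0.00234), fatty acid oxidation (0.00348) and endoplasmic reticulum stress (0.0455). Cell cycle, one-carbon and oxidative phosphorylation genes were also called down in High fry. Those calls used the same Medium libraries and are not independent of these. Without family E the cartilage, fatty acid oxidation, oxidative phosphorylation and stress calls ended (0.448, 0.801, 0.263 and 0.214), the stress call also without family B (0.0961). The fatty acid oxidation and oxidative phosphorylation calls ended without the doubted libraries (0.111 for each). Exact two-sided permutation tests of the list means gave p = 0.01082 for liver and 0.0368 for innate immunity in Low fry at 0 dph. At 14 dph exact permutation gave 0.0411 for one-carbon genes in High fry, and 0.01515 and 0.0346 for cell cycle and one-carbon genes in Low fry, both lower. It gave 0.0476 for fatty acid and triglyceride synthesis genes, which were higher in Low fry (0.13 ± 0.0576) and were not called by the preset test. The adjusted p of these exact tests was 0.833 or more for every list over the 4 comparisons.

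**Figure D2:**
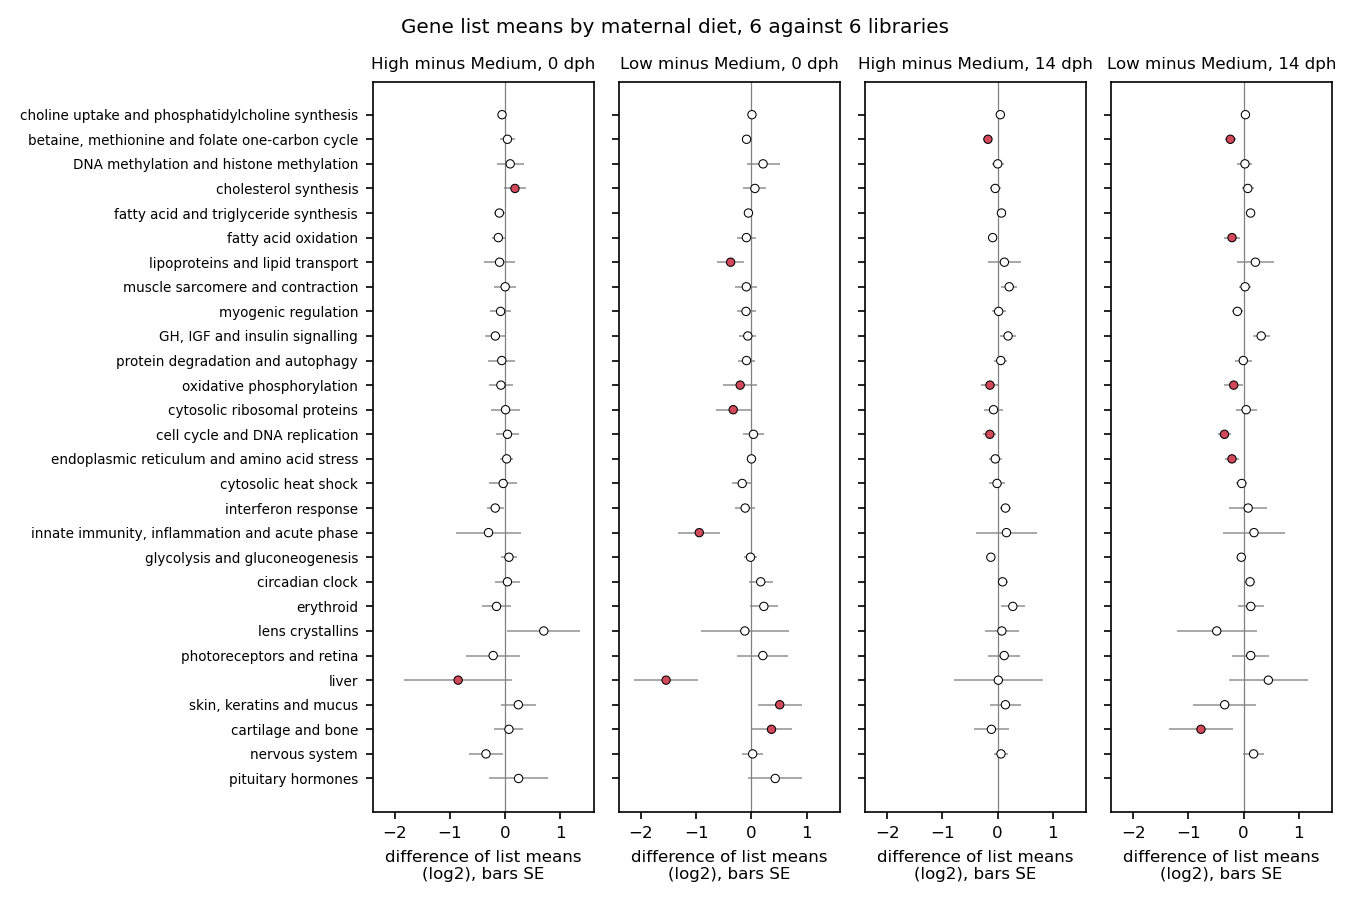
Difference of list means (log2, diet minus Medium, bars 1 SE, 6 libraries per diet) for the gene lists with a mean, 28 at 0 dph and 27 at 14 dph, in the 4 comparisons. Red marks the lists called by the camera test with a preset correlation. The liver list differed by −1.55 ± 0.58 for Low against Medium at 0 dph and the cell cycle list by −0.35 ± 0.12 at 14 dph.

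Among genes named only after their values were seen, adipoqb, related to the fat cell hormone adiponectin, averaged 185 ± 54.0 in Low and 362 ± 68.4 in Medium fry at 14 dph (SD, n = 6). The elongin subunit elob averaged 1748 ± 237 and 2620 ± 241 (log2 fold change −0.59 ± 0.12). The muscle stress gene ankrd1a averaged 138 ± 80.4 and 636 ± 533 (−2.13 ± 0.51), and tamalin 164 ± 16.6 and 99.2 ± 17.8 (0.74 ± 0.19). For all of these the 2 diets did not overlap and the adjusted p was 0.523. Of 35779 genes with a mean of at least 10, 127 (0.355%) did not overlap in that comparison, against 0.216% by chance, with 46 higher and 81 lower in Low fry. For supplementation at 14 dph the number was 40 (0.112%), and at 0 dph it was 24 (0.0663%) for supplementation and 33 (0.0911%) for restriction.

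The comparisons within each family asked whether the offspring of a family responded to the mother's diet, with 2 libraries per diet. In family E at 14 dph the lysosomal protease genes ctsbb (log2 fold change −3.61 ± 0.58, adjusted p = 0.0244), ctsa (−1.81 ± 0.33, 0.0277) and ctsk (−2.51 ± 0.52, 0.0387) were lower in Low fry. The fit was that of all 9 diet and family cells, which pools the spread of the 18 libraries. Also lower were the cartilage collagen col11a1a (−2.31 ± 0.41, 0.0273), the keratin krt18b (−1.54 ± 0.29, 0.0303) and the methylated DNA reader mbd2 (−2.11 ± 0.45, 0.0398). The synaptic gene sv2a (1.02 ± 0.22, 0.0396) and the erythroid membrane gene epb41a (1.89 ± 0.39, 0.038) were higher. The RNA polymerase II subunit gene polr2c is listed at 0 in both Low E libraries and at 356 and 239 in the Medium E libraries (adjusted p = 1.84e-06). In tables without read counts a value of 0 does not show that a transcript was absent. This fit called 864 genes in family E for restriction at 14 dph, 291 up and 573 down. The span correlation was 0.224 in Low E1 and 0.264 in Low E2, against −0.138 and 0.0242 in Medium E1 and E2. With it as a covariate the fit called 2 genes, polr2c and LOC118946045. The median size over the 864 genes went from 1.81 to 1.52 and the median SE from 0.375 to 0.512. In family A it called LOC110487443 for supplementation at 0 dph, listed at 0 in both High libraries and at 66.9 and 86.1 in Medium. It also called LOC110535793 (−3.26 ± 0.32) and LOC118936472 (−4.59 ± 0.56) for restriction at 14 dph. These 3 were named after their values were seen. It called 0 genes in the other 9 family comparisons, with 374 to 2163 at an unadjusted p under 0.05.

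The 864 calls depended more on Low E1 than on Low E2: without Low E1 the fit called 5 genes, all among the 864, and without Low E2 it called 6844, with 843 of the 864 among them. Over the 864 genes Low E2 lay on the same side of the Medium E mean as Low E1 in 100%, by a median of 1.33 against 2.22 (log2). The genes were picked by the mean of both libraries against that Medium E mean, so agreement in side was largely fixed by the choice. Of these 864 genes 43.4% had the same sign in family A and 41.1% in family B. With each family fitted alone limma called 0 genes in all 12 comparisons, with 795 to 7091 at an unadjusted p under 0.05, the highest for restriction in family E at 14 dph. The authors' deposited table lists 3701 genes for that comparison, 160 for restriction in family A at 14 dph and 118 for supplementation in family E at 0 dph. The other 9 family tables list 3 to 15. By the authors' deposited table, family A fry of Low mothers had log2 fold changes of 4.07 for igfbp1 (adjusted p = 0.0433), 5.64 for the mucin muc2.1 and −3.24 for ankrd1a at 14 dph and −4.85 for lect2 at 0 dph. At 14 dph the liver list stood at −3.32 in Medium A1, −0.22 in Medium A2, 0.82 in Low A1 and 0.74 in Low A2. In normalized counts lect2 at 0 dph was at 1341 ± 1783 in the 2 Medium A libraries, of which Medium A1 stood at 1.85 for the liver list at that age. The authors' deposited table gives −9.06 for spp2 and −8.50 for the bile salt pump gene abcb11b in family E fry of High mothers at 0 dph, where the liver list stood at −2.97 in High E1 and −3.35 in High E2. In family B the authors' deposited table gives 3.16 for the eye gene optc and 2.19 for the pigment gene slc45a2 in the same comparison, and −1.26 for selenof for restriction at 14 dph.

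**Figure D3:**
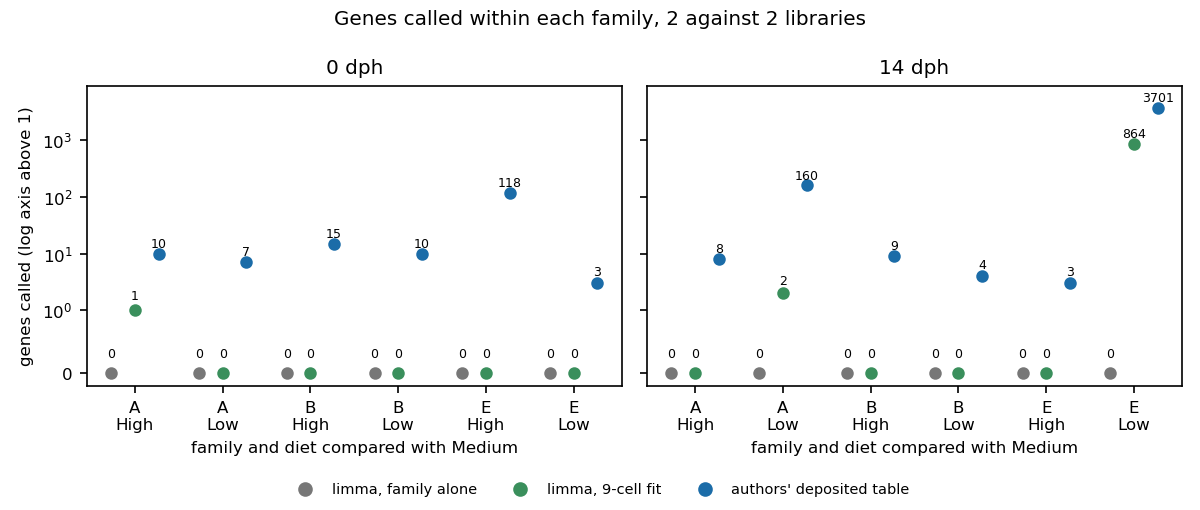
Genes with an adjusted p under 0.05 per family and comparison (log axis above 1) by limma in each family alone, by the 9-cell fit and in the authors' deposited table. Restriction in family E at 14 dph stands apart with 864 genes in the 9-cell fit and 3701 in the authors' table.

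Within each sire 3 libraries were compared per diet. The long non-coding RNA gene LOC118936708 was called in sire 2 at 14 dph for both contrasts (adjusted p = 0.02), being listed at 0 in the 3 High and the 3 Low libraries and at 62.8 to 215 in Medium. Both contrasts share these Medium libraries. In sire 1 at 0 dph LOC118938158 was called for supplementation (adjusted p = 0.00761), listed at 0 in the 3 High libraries and at 46.9 to 65.4 in Medium. This call ended when any single one of its Medium or High libraries was left out. The 6-cell fit called 0 genes in that comparison and 0 for restriction in sire 2 at 14 dph. Both genes were named after their values were seen. Limma called 0 genes in the other 5 sire comparisons, with 680 to 2410 at an unadjusted p under 0.05. In the 3 comparisons with 1 call these counts were 765, 2268 and 3983. The authors' deposited table lists 5 to 55 genes per sire comparison, among them the glycosylation gene alg2 in sire 2 for supplementation at 14 dph (log2 fold change −5.48). In limma alg2 had −5.24 ± 0.56 in that comparison (n = 3 per diet, adjusted p = 0.133).

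Whether the response differed between families or sires was tested as an interaction. For restriction at 14 dph limma called polr2c in the test of families (0.38 and −0.19 in families A and B, adjusted p = 0.000105), a call that rests on the 0 in both Low E libraries. It also called LOC118946045, LOC110496850, LOC110503180, LOC110496917 and LOC110509581 (adjusted p = 0.036 for each). Each of these had its largest fold change in size in family E (−5.68, 2.01, −2.35, −8.16 and −2.10). With a family left out this test called 0 to 1 genes, and with a larger SE it called 1. The lysosomal gene fuca2 (0.67, 0.90 and −2.71 in families A, B and E, adjusted p = 0.0598), the stress gene nupr1b (1.52, −0.39 and −1.91, 0.091), vill (1.79, −2.02 and 2.05, 0.106) and ctsbb (0.50, 1.33 and −3.61, 0.132) were among those with informative names and the next smallest p, with dtx3l1 (0.0859) and tgm1l1 (0.132). For restriction at 0 dph the response of LOC110496918 differed between sires (−4.84 in sire 1 and 4.59 in sire 2, adjusted p = 0.000644). Limma called 0 genes in the other 6 interaction tests, with 847 to 1587 at an unadjusted p under 0.05. The counts were 5840 and 4447 in the tests with 6 calls and 1 call. Among those other tests the smallest p with an informative name belonged to ly6pge, p2rx2, nppb, ncx, alg2 and fam163ba, all with an adjusted p of 0.961 or more.

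Across genes, which are not independent replicates, fold changes of different families were little related (Spearman from −0.18 to 0.105 over 12 pairs). Those of supplementation and restriction over all families correlated at 0.322 at 0 dph and 0.512 at 14 dph. The means were 0.456 and 0.449 in 100 simulated draws without change that shared the Medium libraries. When the Medium libraries were divided between the contrasts, the correlation was −0.185 at 0 dph and 0.0519 at 14 dph.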

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

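Of the tests given in this part, those of separate handling and gene span in Low family E, of swaps within family and sire, of the genes called for supplementation in family E, of tissue genes among the authors' calls, and of the tables over all families were chosen only after the result was seen.

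Liver transcripts differed widely between libraries of the same diet: at 14 dph Medium A1 stood at −3.32 (nearest −0.22) and High A1 at −3.35 (nearest −0.11), each far from the other 5 of its group. Ribosomal RNA carried over into the libraries is argued against, since the liver mean did not fall with its share over 18 libraries (Spearman 0.393 at 0 dph and 0.0795 at 14 dph). Less liver tissue in some libraries stays open, as the members moved together with a median pairwise Pearson r of 0.837 at 0 dph and 0.822 at 14 dph. Maternal diet stays open too, with a smallest exact permutation p of 0.01082 for Low against Medium at 0 dph (adjusted p = 0.833), where diet took 16.7% and family 33.6% of the variance. The same axis may lie behind the authors' lower calls for High against Medium in family E at 0 dph: the 104 of 114 called genes outside the liver list had a median r of 0.887 with the liver mean over the 12 libraries of families A and B, against −0.0109 for all genes.

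Restriction in family E at 14 dph gave 864 calls in the 9-cell fit and 3701 in the authors' table, and Low E1 stood apart in its group for lens crystallins (−3.73, nearest −0.36) and innate immunity (−1.96, nearest −0.08). Quantification of the 2 Low E libraries with another set of genes is argued against. Of genes with a mean of at least 50 elsewhere 12 are listed at 0 in both, and the other pairs of a diet and family had 3 to 14 such genes. Separate quantification with the same set of genes need not give such zeros, so this count cannot decide on it. A single library standing apart stays open. The deviation of Low E2 from the Medium E mean was 0.546 times that of Low E1 in the median over the authors' calls. Over genes called without Low E2 the ratio was 0.268, with each library set against the median of the libraries of families A and B. Those genes were picked through Low E1, which can lower this ratio, and the 2 ratios have different baselines. Tissue makeup stays open. With the means of the lens, skin, cartilage and liver lists as covariates the fit called 3 genes. The median SE went from 0.375 to 0.554 and the median size from 1.81 to 0.964. Of 59 tissue genes 2 were among the 864 (Fisher's exact p = 0.332). Of the 56 in the authors' test 18 were among the 3701 (Fisher's exact p = 1.64e-05), where 10.9% of all genes were called. A trend with gene span, a possible sign of RNA quality, stays open as well. With the span correlation as a covariate the fit called 2 genes, but the median size went only from 1.81 to 1.52 and the SE from 0.375 to 0.512. Separate handling cannot be told apart from the diet of family E, because exactly these 2 libraries lack a mark for merged data in their descriptions that the other 16 carry; a response of family E itself is untested.

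The authors' tables over all families differ from the mean over families. An average over families and sires is argued against: the median absolute log2 difference from it was 0.136 or more, with r across genes (which are not independent replicates) of 0.239 to 0.684. A coefficient at a reference family and sire may account for them, since the median difference was at most 0.0281 and r 0.818 to 0.969. Of their calls at 14 dph 80 of 99 and 144 of 174 lay beyond a log2 fold change of 14, such as dut, an enzyme of nucleotide metabolism (24.30 in the authors' table; 3.23 ± 1.97 in limma). No biological explanation was tested.

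A library lay far from its group in 26 measures, where 9.15 are expected by chance. Sums are in units of 1000000 normalized counts and list means are log2 values relative to the median of the 18 libraries of an age. In the Medium group at 0 dph these were the stress list in Medium E2 (−0.40) and pituitary hormones in Medium A1 (1.32). High B2 at 0 dph had a sum of 90.2 (nearest 45.4), a cholesterol synthesis mean of −0.81 and a protein degradation mean of 1.07. Other High libraries at 0 dph were High E2 for glycolysis (−0.52), High E1 for erythroid genes (0.91) and High A2 for skin (−1.15) and pituitary hormones (−2.01). Low B1 at 0 dph had a sum of 74.8 (nearest 40.8), 0.66 for lipoproteins and 1.05 for oxidative phosphorylation, and Low E2 had 0.54 for growth hormone and insulin signalling. At 14 dph Medium B1 had a sum of 57.8 (nearest 34.5) and a ribosomal RNA share of 49.5% (nearest 20.6), and Medium A1 had −0.25 for cholesterol synthesis and −1.49 for lipoproteins. High A1 at 14 dph had a sum of 57.9 (nearest 33.7), −0.34 for fatty acid synthesis and −0.54 for lipoproteins, High B1 had 1.00 for erythroid genes, and Low B1 had 0.36 for myogenic regulation.

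Responses that differed between groups by an interaction test were those of LOC110496918 between sires for restriction at 0 dph (adjusted p = 0.000644) and, between families for restriction at 14 dph, of polr2c (0.000105), LOC118946045, LOC110496850, LOC110503180, LOC110496917 and LOC110509581 (0.036 each). With family labels permuted within each diet 100 times, chance can be excluded for these 6 calls if this test is taken alone (4 of 100 gave as many). It cannot be for the 8 interaction tests together, of which this had the lowest share, and the highest other regrouping called 696, which points to a structure of the samples. For the sire test with 1 call at 0 dph chance cannot be excluded (9 of 100, highest other 4), nor for the tests with 0 calls: families for supplementation and restriction at 0 dph, whose highest regroupings called 781 and 1010, families for supplementation at 14 dph (3), and sires for supplementation at 0 dph (2) and for supplementation and restriction at 14 dph (1 and 13). With 0 calls every regrouping gives as many, so the share could not have excluded chance in these tests.

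For genes over all families the real split called 0 in all 4 comparisons. The other splits called at most 1, 1, 2 and 4 in the order of 0 dph supplementation, 0 dph restriction, 14 dph supplementation and 14 dph restriction. With 0 real calls every split counts as having as many (100 of 100 each). That outcome was fixed beforehand, so chance cannot be excluded by it. Nor can it be for the lists called when adjusted within a comparison, which numbered 2, 7, 3 and 7 with as many in 97, 47, 91 and 51 of 100 splits and 14 in the highest other of each. Swaps of the diets within family and sire, fitted with these as a block, did not exclude it either. Adjusted within a comparison, 2, 7, 3 and 6 lists were called, with as many in 32, 19, 25 and 21 of 32 swaps and 13, 11, 9 and 14 in the highest other. Adjusted over the 4 comparisons together, the same fit of the real diets called 3, 7, 4 and 6. Within a sire the 10 splits of 3 against 3 are too few for a share under 0.05. At 0 dph the real and highest other counts were 1 and 1 (supplementation, sire 1; 3 of 10), 0 and 5 (supplementation, sire 2), 0 and 2 (restriction, sire 1) and 0 and 1780 (restriction, sire 2), the last for Medium A2, Low A2 and Low E2 against Medium B2, Medium E2 and Low B2, which points to a structure of these samples: the span correlation was 0.249, 0.308 and 0.288 in the former and −0.341, −0.228 and −0.109 in the latter. At 14 dph they were 0 and 1 (supplementation, sire 1), 1 and 1 (supplementation, sire 2), 0 and 3 (restriction, sire 1) and 1 and 3 (restriction, sire 2).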

How the results depend on the processing

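The weights, the liver and span covariates, the fits without the doubted libraries, the pooled fits of 9 and 6 cells, the estimated correlation, the exact test of list means, the block for lists and the authors' deposited adjusted p were chosen only after the data were seen; the other settings were planned. Of the recomputed counts and correlations, 451 stayed close (counts within 1.5 times that reported), 56 were larger and 37 smaller. Of the recomputed values for single genes and lists, 2449 kept their side of the threshold (if uncalled, of any sign), 85 fell short of it, 1 passed it and 2 reversed. Where a result changed, the cause was not tested.

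The count of 0 genes over all families stayed at 0 under other thresholds, a minimum fold change, a minimum mean of 10, a pseudocount of 0.5, trimmed-mean scaling, weights, the liver covariate and each library left out. Without the doubted libraries restriction at 0 dph gave 1 gene (LOC110516435). With families left out, restriction at 14 dph gave 0 to 4: 1 without family A (polr2c), 4 without family B (polr2c, LOC110535793, LOC118936472 and LOC118946045) and 0 without family E; these genes were named after their values were seen. Adjustment over every gene without a filter is the fit itself, so it gave no value of its own.

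With the block of family and sire, genes stayed at 0 in all 4 comparisons, and the lists called were 3 and 7 at 0 dph and 4 and 6 at 14 dph for supplementation and restriction, against 2, 7, 3 and 6 without it. The lists gained were lens crystallins at 0 dph (adjusted p = 0.0118) and erythroid genes at 14 dph (0.0441), both up for supplementation. The list-adjusted p was 0.0052 and 0.00729 for igfbp1 (supplementation and restriction at 0 dph), 0.0665 for tlr2, 0.0386 for mat2aa and 0.0296 for sardh, so the call of tlr2 ended.

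The authors' deposited adjusted p gave more calls than limma within families and sires. Over all families, where the authors' tables hold another comparison than the limma fit, the counts were 19 and 20 at 0 dph and 99 and 174 at 14 dph, for supplementation and restriction. For supplementation at 0 dph families A, B and E had 10, 15 and 118 and sires 1 and 2 had 6 and 21; for restriction at 0 dph these were 7, 10, 3, 10 and 14. At 14 dph they were 8, 9, 3, 5 and 19 for supplementation and 160, 4, 3701, 12 and 55 for restriction.

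In the 9-cell fit family A had 1 call for supplementation at 0 dph and 2 for restriction at 14 dph, and family E had 864 for restriction at 14 dph, 5 without Low E1 and 6844 without Low E2, where the lone Low E library is assumed to vary like the other groups. Fitted alone, that comparison gave 0 to 1204 with single libraries left out, 1 without Low E1 and 1204 without Low E2. Sire 1 for supplementation at 0 dph, with 1 call, gave 2 at a threshold of 0.1, 0 in the 6-cell fit and 0 to 1 with single libraries left out, 0 without any of its Medium or High libraries. Sire 2 for supplementation at 0 dph gave 2 in the 6-cell fit and 0 to 1 with single libraries left out (1 without High E2), and for restriction 1 in the 6-cell fit. Sire 1 for supplementation at 14 dph gave 0 to 1 (1 without High A1). Sire 2 at 14 dph, with 1 call for each contrast, gave 0 at a threshold of 0.01 for both, 0 in the 6-cell fit for restriction, and 0 to 4 with single libraries left out for both, 4 without Medium A2. Without High B2 the counts were 2 and 3 for supplementation and restriction, without Low B2 0 and 2, without Medium E2 1 and 0, and without Medium B2, High A2, High E2, Low A2 or Low E2 0 for both. The 6 genes whose response to restriction at 14 dph differed between families became 1 with a larger SE, 10 with a minimum mean of 10, 18 at a threshold of 0.1 and 0 to 1 with a family left out (1 without A, 1 without B, 0 without E). The same test at 0 dph could not be fitted without the doubted libraries, which include both High E libraries.

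With the span correlation as a covariate genes over all families stayed at 0, and 3 and 5 lists at 0 dph and 4 and 6 at 14 dph were called. The calls ended numbered 5 (adjusted p from 0.0551 to 0.48). Gained were fatty acid oxidation (0.0246) and oxidative phosphorylation (0.000468), both down, for supplementation at 0 dph and, all up at 14 dph, erythroid genes (0.0457) for supplementation and growth signalling (0.0372) and liver (0.0235) for restriction. In the 9-cell fit with it, restriction at 14 dph gave 1 gene in family A (LOC110535793) and 2 in family E (polr2c and LOC118946045), and family A for supplementation at 0 dph 0.

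For the lists, a preset correlation of 0.05 gave 1 for supplementation at 0 dph, 1 for supplementation at 14 dph and 3 for restriction at 14 dph. The calls it ended were cholesterol synthesis (adjusted p = 0.11) for supplementation and lipoproteins (0.0931) and cartilage and bone (0.0974) for restriction at 0 dph. At 14 dph they were one-carbon (0.0649) and cell cycle (0.0698) for supplementation and fatty acid oxidation (0.0698), oxidative phosphorylation (0.0856) and stress (0.206) for restriction. A minimum mean of 10 gave 4 for supplementation at 0 dph. The estimated correlation and the exact permutation of list means each gave 0 in all 4 comparisons. With a family left out the counts were 6 to 7 for supplementation at 0 dph, 4 to 6 for supplementation at 14 dph and 9 to 10 for restriction at 14 dph. The liver list for supplementation at 0 dph reversed to up without family E (0.0196) and without the doubted libraries (1.45e-07), with adjusted p from 4.97e-18 to 0.0196 over the families left out. Calls kept with every family left out were, for restriction, liver (4.41e-21 to 4.04e-16), innate immunity (2.58e-08 to 0.00239) and ribosomal proteins (2.04e-09 to 0.00446) at 0 dph and the cell cycle (3.01e-06 to 0.000487) and one-carbon cycle (0.00855 to 0.0444) at 14 dph. With single libraries left out the list-adjusted p was 3.26e-05 to 0.0239 and 0.00037 to 0.035 for igfbp1 at 0 dph, 0.00623 to 0.0716 for tlr2 (0.0531 or more without Medium A2, B2, E1 or E2 or Low A2, B1 or E2), 0.00704 to 0.0735 for mat2aa, and 0.00931 to 0.0735 for sardh. Genes near 0 such as tlr2 and vtg3 rest on few normalized counts.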

Other observations

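Some genes differed between families or sires with the diets pooled, in comparisons chosen after the data were seen. Whether these differences were the same in each diet was not tested. At 0 dph LOC118936788 was higher in family B than in family A (log2 fold change 6.84 ± 0.74, 6 libraries per family, adjusted p = 0.00133), averaging 216 ± 139 against 0.262 ± 0.406 normalized counts. The Golgi trafficking gene cog4 was higher in sire 2 than in sire 1 (1.47 ± 0.23, 9 libraries per sire, adjusted p = 0.0454), at 181 ± 66.8 against 61.6 ± 14.5. Limma called 2 genes between families B and A, 2 between E and A, 5 between E and B and 6 between sires at 0 dph; at 14 dph the counts were 2, 0, 0 and 6, with 2668, 2823, 3180 and 3692 genes at an unadjusted p under 0.05.

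Several fixed lists that the preset camera test of the main fit called in no comparison over all families still had members to describe. Growth hormone, insulin-like growth factor and insulin signalling had 20 of 28 members above 0 in Low fry at 14 dph (adjusted p = 0.0579 by that test). With the span correlation as a covariate the test called this list (adjusted p = 0.0372). DNA and histone methylation genes had 13 of 15 above 0 in Low fry at hatch (adjusted p = 0.473). The mean of the latter list had a Spearman correlation of 0.899 with the span correlation over the 18 libraries of that age. With the span correlation as a covariate its direction turned down (adjusted p = 0.882). Lens crystallins had 6 of 6 members above 0 in High fry at hatch, with a median log2 fold change of 0.67 (adjusted p = 0.0547). With family and sire as a block the preset test called this list (adjusted p = 0.0118). The difference of list means was 0.49, 1.77 and −0.16 in families A, B and E. In 3 of 6 High libraries the list lay above the Medium library of the same family and sire. Its Spearman correlation with the span correlation was −0.744. In Low fry at 14 dph 6 of 6 lens members were below 0, with a median of −0.37 (adjusted p = 0.336). In that comparison Low E1 stood apart at −3.73 (nearest −0.36), and the difference of list means was 0.46, −0.21 and −1.72 in families A, B and E. In the authors' deposited table for restriction in family E at 14 dph, the cartilage genes cnmd and otos2 had log2 fold changes of −4.41 and −4.29, and the steroid enzyme gene hsd17b3 and the calcium exchanger slc8a1a 4.99 and 4.19. The authors' deposited table for sire 2 gave −2.52 for ankrd1a and −1.97 for the myosin light chain mylpfb for restriction at 14 dph, and 1.23 for enc3 for supplementation at 0 dph. At an adjusted p of 1, the interleukin receptor il17rc (1.68 ± 0.48) and tacr2 (−1.74 ± 0.50) in High fry and kl (−1.96 ± 0.53) and f7l (−2.75 ± 0.81) in Low fry at hatch, and cartl (4.14 ± 1.07) in High fry at 14 dph, were named after their values were seen.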
